A study of Drosophila melanogaster with 11 samples.

How the data were processed

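The study measured total RNA of whole third-instar larvae on Affymetrix Drosophila 2.0 arrays, 1 labelled cRNA sample per array. The deposited values, 1 per probeset and array, are intensities on the linear scale that the authors normalized and summarized with RMA. The labels give no version or options of RMA, nor whether all arrays were normalized together. The linear scale was checked on the values, which are all above 0 and reach 11947 to 13617 per array. Log2 was taken of every value before any other step, with no pseudocount and no filter on low values. No background level was estimated and no detection calls were used. Where a log2 mean is called not told apart from background below, it was at most 4.16, a level above the median of every array. This cut was not tested, and the lower bounds given for changes from such means rest on it.

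The table has 18952 probesets, of which 183 Affymetrix control probesets were left out of the tests and 18769 were tested. Of these, 13647 are assigned to 1 gene, 402 to several and 4720 to none by the platform table, and 13544 of the single-gene probesets had a chromosome in the RefSeq gene table. For counts of genes and for gene lists, each of 11982 genes was represented by its probeset with the highest mean over all 11 arrays. No array was left out. Arrays were grouped by genotype and sex into 6 groups, from the titles, with 2 arrays per group and 1 in P/act-Gal4 female; the strain and description labels conflict with titles and genotypes for some arrays and were not used. The design text speaks of 2 independent larval populations but the labels do not say which array came from which, so populations were not modelled.

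Group means were fitted per probeset to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual degrees of freedom, 6.29 prior degrees of freedom). The lone P/act-Gal4 female array is assumed to vary like the other groups. There were 6 comparisons: P/act-Gal4 minus the mean of both controls in males and in females, the difference between these, male minus female controls, and act-Gal4 minus P control in each sex. P-values of limma's moderated test were adjusted by the Benjamini-Hochberg method over the probesets of a comparison, and a probeset was called at an adjusted p under 0.05. Errors of log2 changes are standard errors of the fit. Figures were drawn with matplotlib 3.10.9.

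Of 27 gene lists, 25 with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; camera compares a list's genes with all others. The 3 measured histone genes and the 1 measured transgene marker were too few for a test of the list. The lists cover heterochromatin proteins, dosage compensation, pericentric heterochromatin genes, chromosome 4 genes, the RNA interference and small RNA pathway, DNA replication and cell cycle, heat shock, immune genes, testis, ovary, sex determination, the ecdysone response, salivary glue, fat body, midgut digestion, larval cuticle, muscle, nervous system, hemocytes, imaginal discs, xenobiotic metabolism, ribosomal proteins, mitochondrial respiration, glycolysis, and DNA damage and apoptosis. Genes of 6 chromosome groups (X, 2L, 2R, 3L, 3R and 4) were tested in the same way as a family of their own. Genes were named by a rule: per comparison among those of males, females, their difference and sex in controls, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, 1 symbol that is not a bare CG or CR number, and arrays of the groups not overlapping (not asked for the difference between sexes). The HP1 gene, Su(var)205, and up to 4 passing members of each list with the largest change were added, or 2 members as values where none passed. The grouping, comparisons, lists, naming rule and alternatives were chosen before the data were examined, except where the text says otherwise.

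Alternatives to each choice were limma's trend and robust options, array weights, bright probesets only, a further quantile normalization, a shift of all arrays to a common median, 1 probeset per gene, an adjusted p under 0.1, a change of at least 1 on the log2 scale, leaving out each array in turn, each control alone, both controls pooled, and arrays of 1 sex only; for lists, camera with an estimated correlation and fry. The procedure was tested on simulated data with 50 changed probesets at each size. Apart from these and a shifted gene list, the simulated arrays held independent normal noise, without differences of sex or cross. Far fewer probesets changed than were called in the real arrays. The shares below therefore need not hold for these data and do not cover differences between crosses. In males it called 4% of changes of 0.25 on the log2 scale, 50% of 0.5, 96% of 1 and 100% of 2, with 3 false calls (2.21% of calls). In females, with 1 array, it called 0%, 22%, 88% and 100%, with 7 false calls (6.25%). For the difference between the sexes, with 100 changed probesets at each size, it called 0%, 10%, 74% and 100%, with 18 false calls (8.91%).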

Results

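Total RNA from whole third-instar larvae of Drosophila melanogaster was measured on 11 Affymetrix Drosophila 2.0 arrays, 6 from males and 5 from females. The larvae carried, in a y w background, the act-Gal4 driver alone (act-Gal4 control), the transgene labelled P alone (P control), or both (P/act-Gal4). P was read as line HP1-21 of the design text, which is taken here to carry an RNA interference construct against HP1 that acts where the Gal4 activator is made. Every group held 2 arrays, except P/act-Gal4 females, with 1. Median intensity lay between 15.3 and 15.6 on the male arrays and between 13.6 and 14.1 on the female arrays, and the number of arrays limits the precision. Replicates of a group differed by a median of 0.0925 to 0.135 on the log2 scale. Their correlation across probesets, which are not independent replicates, was 0.994 to 0.998, against 0.908 to 0.930 between the sexes. The log2 difference between the 3′ and 5′ probesets of eIF4a, a measure of RNA integrity and labelling, was 4.32 in act-Gal4 control males, 4.96 in P control males and 3.69 in P/act-Gal4 males. It was 4.22, 3.95 and 3.47 in the same order in females.

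Whether the HP1 transcript was lower where both transgenes were present was asked for each sex. The gene of HP1, a chromatin protein of pericentric heterochromatin and chromosome 4, lies on arm 2L and has 1 probeset. Its transcript fell in P/act-Gal4 males by 0.53 ± 0.0943 (SE) on the log2 scale, a 1.44-fold fall (adjusted p = 0.00124). The mean was 8.21 over 4 control arrays and 7.68 over 2 P/act-Gal4 arrays. The male controls themselves stood apart, at 8.05 for P and 8.37 for act-Gal4 (difference 0.32, adjusted p = 0.0674). The fall was therefore smaller against the P control alone (−0.37, adjusted p = 0.0264) than against the act-Gal4 control alone (−0.69, adjusted p = 0.000589). Both P/act-Gal4 male arrays, at 7.84 and 7.52, lay below all 4 male control arrays, at 8.03 to 8.39. On the array labelled P/act-Gal4 female the transcript was not lower, at 8.02 against a control mean of 8.02. The log2 change there was −0.0017 ± 0.122 (adjusted p = 0.994), with a 95% interval of −0.27 to 0.27. The difference between the sexes was −0.53 ± 0.154 (adjusted p = 0.0467). It did not pass against the P control alone (−0.38, adjusted p = 0.189), with both controls pooled (adjusted p = 0.327), with quantile normalization applied once more (adjusted p = 0.0582), or without any single array other than P control female replicate 2 and P/act-Gal4 male replicate 1 (adjusted p = 0.0592 to 0.162). Every statement below on females with both transgenes rests on 1 array, in which the HP1 transcript was not lower.

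**Figure D1:**
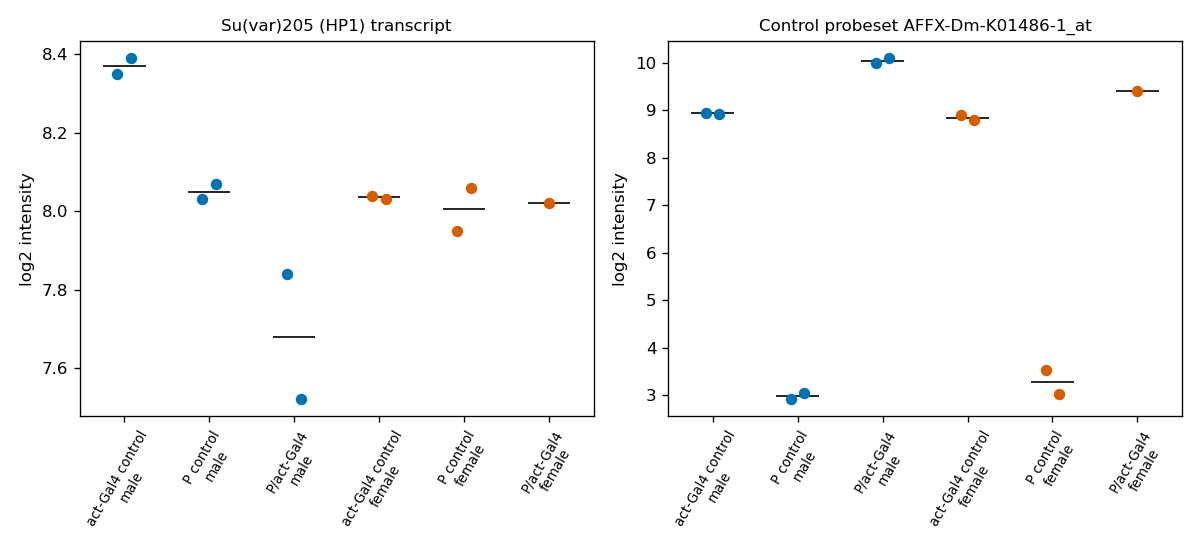
Log2 intensity of the HP1 probeset (left) and of the control probeset AFFX-Dm-K01486-1_at (right) on each of the 11 arrays, as points in the 6 groups, with a bar at each group mean. Both P/act-Gal4 male arrays lie below all male control arrays for HP1, at 7.84 and 7.52, and the array labelled P/act-Gal4 female lies at 8.02 among the female controls.

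The question in males was which transcripts differ in larvae with both transgenes (n = 2) from the mean of both controls (n = 4). Among named genes, the largest rise belonged to an 18S ribosomal RNA pseudogene on the X, 18SrRNA-Psi:CR41602, by 4.05 ± 0.0898 on the log2 scale (16.5-fold, adjusted p = 1.56e-10). Jig rose 6.53-fold, the antimicrobial peptide gene Def 6.04-fold, acs 4.59-fold and the cathepsin gene CtsL3 4.44-fold. The cytochrome P450 genes Cyp4e3 and Cyp6w1 rose 4.93-fold and 3.34-fold. The ebony gene (e), which acts in tanning of the cuticle, rose 3.95-fold. Rises of Eig71Ed, an ecdysone-induced gene, and LManIII, a lysosomal mannosidase gene, were 3.61-fold and 3.53-fold. The deepest falls among named genes were those of nol (−3.93 ± 0.0981, 15.3-fold), the ecdysone-inducible gene ImpE2 (−3.76 ± 0.0788, 13.6-fold) and the larval cuticle gene Lcp9 (−3.46 ± 0.0743). The alkaline phosphatase genes Alp8 and Alp7 fell 4.84-fold and 4.22-fold, the salivary glue gene Sgs1 4.43-fold and Hsp68 4.28-fold. The cuticle gene Cpr92F fell 4.12-fold, Nplp4 3.92-fold and the chitinase gene Cht10 3.55-fold. The lower of the means compared was 3.24 to 3.84 for ImpE2, Cpr92F, Eig71Ed, 18SrRNA-Psi:CR41602, Alp7, nol and Def, levels not told apart from background, so that their folds are lower bounds. All 20 of these genes passed against each control taken alone, though sizes differed: Cyp4e3 rose by at least 3.95 on the log2 scale against the P control, whose mean of 3.99 was as low so that its 4.93-fold is a lower bound too, and by 0.66 against the act-Gal4 control, and Hsp68 fell by 3.30 and by 0.90. With both controls pooled 8 of the 20 did not pass, namely Hsp68 (adjusted p = 0.0771), acs (0.0862), LManIII (0.155), Alp7 (0.190), Cyp4e3 (0.229), Alp8 (0.249), CtsL3 (0.293) and e.

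Genes of energy metabolism and of cell division were lower in P/act-Gal4 males. Of 75 measured genes of mitochondrial respiration, 52 fell and 5 rose (55 and 6 adjusted over the list alone). Their median log2 change was −0.39 (camera adjusted p = 3.43e-11, and adjusted p = 0.105 with an estimated correlation). Examples are the cytochrome oxidase subunit gene levy (−0.83 ± 0.0743), RFeSP of complex III (−0.82 ± 0.077) and ATPsynbetaL (−1.12 ± 0.191). The list was formed by gene name and also holds genes far higher in control males than in control females, such as ATPsynCF6L, COX5BL and COX4L. Of 53 genes of DNA replication and the cell cycle, 25 fell and 2 rose (26 and 3 adjusted over the list alone). Here the median was −0.21 (camera adjusted p = 1.8e-05, and adjusted p = 0.105 with an estimated correlation). Mcm6 and Mcm5, subunits of the replicative helicase, fell by 0.98 ± 0.0928 and by 0.84 ± 0.134. The cyclin gene CycB3 fell by 0.95 and fzy, an activator of the anaphase-promoting complex, fell by 0.99. Of 17 genes of glycolysis and sugar metabolism, 9 fell and 3 rose (9 and 4 adjusted over the list alone), with Tpi at −0.82, Ald1 at −0.82 and Hex-A at 0.75. The median of this list was −0.30 (camera adjusted p = 0.0456, and adjusted p = 0.195 with an estimated correlation), a call that ended without P control male replicate 2 (adjusted p = 0.0533) or P/act-Gal4 male replicate 1 (adjusted p = 0.0537). The eIF4a 3′ minus 5′ difference was lower by 0.96 in the same males than the mean of the controls.

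Of 34 genes of heterochromatin proteins, 15 fell and 4 rose in P/act-Gal4 males (15 and 5 adjusted over the list alone). Their median was −0.17 (camera adjusted p = 0.0217, adjusted p = 0.195 with an estimated correlation, and 0.0644 with bright probesets alone). With 1 array left out this median ran from −0.20 to −0.098. Besides the HP1 gene these included Incenp of the chromosomal passenger complex (−0.98 ± 0.111), HP4 (−0.81 ± 0.106), the HP1 paralog HP1b (−0.70 ± 0.0909) and the lamin B receptor gene LBR (−0.65 ± 0.108). Of 3 measured histone genes, too few for a test of the list, His2Av fell by 0.90 ± 0.0741, cid stood at −0.19 (adjusted p = 0.0977) and BigH1 at −0.53 (adjusted p = 0.0156). The call of BigH1 ended without P control male replicate 2 (adjusted p = 0.0514), P/act-Gal4 male replicate 1 (0.0588) or P/act-Gal4 male replicate 2 (0.151), and against the act-Gal4 control alone (0.082). In the list of dosage compensation, 3 of 10 genes rose and 1 fell (5 and 1 adjusted over the list alone), among them the kinase gene JIL-1 (1.06 ± 0.147). The list itself did not pass (median 0.20, camera adjusted p = 0.235). Among 18 genes of pericentric heterochromatin 3 rose and 3 fell, the same with adjustment over the list alone, with Snap25 at 0.81 and Cht10 at −1.83. Median and mean differed in sign, at 0.042 and −0.005 (camera adjusted p = 0.781). Among 23 genes of the RNA interference and small RNA pathway, 4 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.781), with Dcr-2 at 0.52 and mael at −0.67.

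Genes of chromosome 4 were higher in P/act-Gal4 males. Of its 65 measured genes, 32 rose and 2 fell (33 and 2 adjusted over the list alone). The median log2 change was 0.23 (camera adjusted p = 9.51e-05 over 6 chromosome groups, and adjusted p = 0.507 with an estimated correlation). Zip102B, a zinc transporter gene, rose by 1.43 ± 0.132 and CG11155 by 0.80 ± 0.0945. The gene unc-13, which acts in synaptic vesicle release, rose by 0.78 ± 0.0862 and the transcription factor gene dati by 0.75 ± 0.106, which the 1 other, dim probeset of dati did not share. Zip102B also differed between the male controls, by at least 1.33. The rise of the chromosome passed against either control alone, with medians of 0.22 against the P control (adjusted p = 7.1e-05) and 0.19 against the act-Gal4 control (adjusted p = 0.0023). Medians of the other 5 arms lay between −0.019 and −0.005, with −0.016 on the X (adjusted p = 0.951). A list of 39 chromosome 4 genes, fixed by name, gave 14 rises and 2 falls (15 and 2 adjusted over the list alone), with gw, a component of microRNA silencing, at 0.51. Its median was 0.14 (camera adjusted p = 0.0456, and adjusted p = 0.323 with an estimated correlation). This call ended without act-Gal4 control male replicate 2 (adjusted p = 0.0556), P control male replicate 1 (0.079) or P/act-Gal4 male replicate 2 (0.0895).

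**Figure D2:**
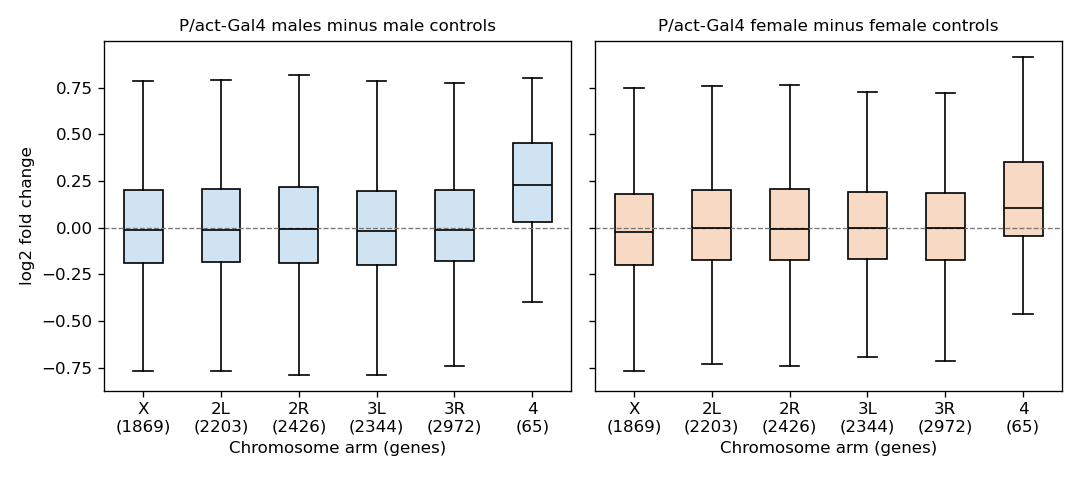
Log2 change of genes by chromosome arm in males (left) and on the array labelled P/act-Gal4 female (right), each against the mean of both controls of the sex; boxes give median and quartiles and whiskers reach 1.5 times the interquartile range. In males the median of the 65 chromosome 4 genes lies at 0.23, and those of the other arms between −0.019 and −0.005.

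Tissue lists moved as well in P/act-Gal4 males. Larval cuticle and epidermis had 18 falls and 4 rises among 50 genes (19 and 4 adjusted over the list alone), with Lcp65Ac at −1.60 ± 0.0833 and Cpr47Eg at −1.57 ± 0.081. The median was −0.14 (camera adjusted p = 0.00235, and adjusted p = 0.105 with an estimated correlation). Salivary gland glue had 8 falls and 1 rise among 16 genes (8 and 1 adjusted over the list alone), with Muc26B at −1.02. Its median was −0.21 (camera adjusted p = 0.0111, and adjusted p = 0.127 with an estimated correlation). Heat shock and protein folding had 7 falls and 2 rises among 13 genes (7 and 2 adjusted over the list alone), with Hsp60A at −0.96. That list had a median of −0.35 (camera adjusted p = 0.0217, and adjusted p = 0.195 with an estimated correlation). Ribosomal proteins had 18 rises and 5 falls among 40 genes (21 and 6 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0217, and adjusted p = 0.209 with an estimated correlation). With quantile normalization that median was 0.063 and did not pass (adjusted p = 0.332). The largest changes in that list were falls of paralogs, RpS19b (−0.99 ± 0.194), RpS5b (−0.82 ± 0.0943) and RpL22-like (−0.76 ± 0.135).

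Among 29 imaginal disc genes 10 fell and 4 rose in P/act-Gal4 males (11 and 4 adjusted over the list alone), including the homeobox gene engrailed (en, −1.22 ± 0.0787) and dac (−1.07 ± 0.123). Their median was −0.14 (camera adjusted p = 0.0456, and adjusted p = 0.195 with an estimated correlation). Among 23 genes of hemocytes and melanization 9 rose and 1 fell (9 and 1 adjusted over the list alone), led by the phagocytosis receptor genes NimC1 (1.54 ± 0.0943) and Sr-CI (1.14 ± 0.0845). The hemocyte median was 0.099 (camera adjusted p = 0.0456, and adjusted p = 0.195 with an estimated correlation), and it ran from 0.096 to 0.158 with 1 array left out. Both calls ended without act-Gal4 control male replicate 2 (adjusted p = 0.0625 for imaginal disc and 0.0514 for hemocyte genes), without P control male replicate 2 (0.0723 and 0.0533) and without P/act-Gal4 male replicate 1 (0.073 and 0.0607).

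The remaining lists did not pass in males. Of all 11982 genes, 4379 passed in males, 2366 higher and 2013 lower, so counts of passing members are not by themselves results about a list. Immune genes gave 5 rises and 10 falls of 30 (6 and 10 adjusted over the list alone, camera adjusted p = 0.241), of which PGRP-SC2 and Drs fell by 1.64 ± 0.0861 and by 1.24 ± 0.0874. Testis genes gave 7 and 17 of 54 (8 and 19 adjusted over the list alone, adjusted p = 0.127). Ovary genes gave 6 and 1 of 28 (6 and 1, adjusted p = 0.224), with exu, which acts in the germline of both sexes, at −1.09 ± 0.0999, and sex determination 2 and 4 of 11 (3 and 4, adjusted p = 0.648). The ecdysone response gave 13 and 6 of 40 (13 and 6, adjusted p = 0.224) and midgut digestion 16 and 15 of 50 (17 and 16, adjusted p = 0.928). Fat body gave 11 and 4 of 26 (12 and 4, adjusted p = 0.096), with the apolipoprotein gene Apoltp at 1.14 ± 0.0836 and the iron carrier gene Tsf1 at 1.06 ± 0.0875. Muscle gave 6 and 10 of 24 (6 and 10, adjusted p = 0.127), with the tropomyosin gene Tm2 at −1.08 ± 0.0734. Nervous system genes gave 9 and 2 of 34 (9 and 2, adjusted p = 0.186) and xenobiotic metabolism 22 and 14 of 75 (23 and 15, adjusted p = 0.256). DNA damage and apoptosis gave 6 and 1 of 23 (7 and 1, adjusted p = 0.178), with the DNA repair gene mre11 at 0.98 ± 0.109.

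In all, 5482 of 18769 probesets passed in males, 3066 higher and 2416 lower in P/act-Gal4 larvae, and 397 of them differed at least 2-fold. Both P/act-Gal4 arrays lay beyond all 4 control arrays, on the same side, for 39.6% of all probesets. Chance would give 13.3% if all male arrays were exchangeable. Replicates of a cross lie closer together than arrays of different crosses, so 13.3% is too low and no excess over chance is read. Among the 5482 called, the number was 4872 (88.9%), a share that the test itself raises. With both controls of a sex pooled into 1 group 2447 passed, 2871 passed against each control separately, and without P/act-Gal4 male replicate 2 the count was 3392. Examples from the lists that did not pass with pooled controls were Hex-A (adjusted p = 0.0587), BigH1, Ald1, Dcr-2, Drs, Zip102B and Cpr47Eg (0.215). Of the examples, ATPsynbetaL, Mcm5, mael, dac, CG11155, NimC1, Sr-CI and Zip102B had means of at most 4.16, not told apart from background, in P/act-Gal4 males or in controls, on the lower side alone, so that their sizes are lower bounds. Such means lay on both sides for LBR, Snap25, BigH1 and Cpr47Eg, whose sizes are thus uncertain. The falls of RFeSP and fzy and the rise of Tsf1 were not shared in sign by 1 other, dim probeset of each. List calls that ended against the P control alone were those of glycolysis (adjusted p = 0.506), ribosomal proteins (0.0769), cuticle (0.061) and glue (0.061). Against the act-Gal4 control alone, those of heat shock (adjusted p = 0.496), hemocytes (0.926), imaginal disc (0.316) and the named chromosome 4 list (0.111) ended. With bright probesets alone, those of the named chromosome 4 list (0.178), imaginal disc (0.122), ribosomal proteins (0.0946), hemocytes (0.0644) and glycolysis (0.0644) ended. Calls of hemocytes and imaginal disc also ended with quantile normalization (0.0688 for both), and those of heat shock (0.0542), glue (0.0514) and glycolysis (0.0514) with pooled controls. The lists of mitochondrial respiration and of DNA replication kept their calls under each of these settings. Against the P control alone, testis (adjusted p = 0.00288), fat body (0.00288) and xenobiotic genes (0.00552) passed, and against the act-Gal4 control alone muscle did (0.0435). Over camera's alternatives for the 8 lists that lost a call with 1 control, adjusted p reached down to 0.0304 for the named chromosome 4 list and lower for the others, and up to 0.105 for cuticle and higher for the others.

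The same question in females compares the array labelled P/act-Gal4 female (n = 1) with the mean of both female controls (n = 4). The ebony gene (e) stood 17.7-fold higher on it (4.14 ± 0.104 on the log2 scale, adjusted p = 3.12e-09), with at least 6.54 against the P control, whose mean of 3.84 was not told apart from background, and 1.74 against the act-Gal4 control. Drsl5, of the drosomycin family of antifungal peptides, rose 8.86-fold, the serpin gene Spn100A 7.42-fold, Eig71Ea 7.18-fold and CtsL3 6.59-fold. The lipocalin gene NLaz rose 4.62-fold, 18SrRNA-Psi:CR41602 4.33-fold, Jig 4.24-fold, the growth-blocking peptide gene Gbp1 4.10-fold and Eig71Ed 3.92-fold. Falls included those of the cuticle genes Cpr47Eg (−2.20 ± 0.105, 4.61-fold), Lcp65Ag3 (4.51-fold), Cpr11B (3.21-fold) and Cpr47Ec (3.02-fold). The mitochondrial phosphate carrier gene Mpcp1 fell 3.57-fold and Obsc of muscle 3.47-fold, a fall that its 1 other, dim probeset did not share. Acbp5 and Acbp4, of acyl-CoA binding proteins, fell 3.28-fold and 3.18-fold, Alp8 3.07-fold and LManVI 2.92-fold. The lower means of Eig71Ed (3.35), Eig71Ea (3.74) and Cpr11B (3.94) were not told apart from background, nor were the P control means of Spn100A (3.88), CtsL3 (4.01), NLaz (3.74) and Gbp1 (3.69), so that the folds of these genes and of e are lower bounds. Of these 20 genes, 19 passed against each control alone, whereas Alp8 stood at −0.36 against the act-Gal4 control (adjusted p = 0.149). With both controls pooled 14 of the 20 did not pass, namely Mpcp1 (adjusted p = 0.0519), Cpr11B, LManVI, Gbp1, NLaz, Cpr47Ec, Acbp5, e, Drsl5, Lcp65Ag3, Acbp4, Cpr47Eg, CtsL3 and Alp8 (0.658).

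On the array labelled P/act-Gal4 female, 49 of 75 genes of mitochondrial respiration fell and 1 rose (53 and 1 adjusted over the list alone). The median was −0.53 (camera adjusted p = 5.33e-20, and adjusted p = 0.0235 with an estimated correlation, as also for glycolysis, muscle and the ecdysone response). ND-75 of complex I fell by 1.30 ± 0.103, SdhB of complex II by 1.06 ± 0.0982 and Cyt-c1 of complex III by 1.03 ± 0.0949. Glycolysis and sugar metabolism had 13 falls and 1 rise among 17 genes (13 and 1 adjusted over the list alone), with Pfk at −1.21 ± 0.107 and Eno at −0.93 ± 0.102. Its median was −0.59 (camera adjusted p = 8.89e-08). Muscle had 12 falls and 1 rise among 24 genes (15 and 1 adjusted over the list alone), with a median of −0.36 (camera adjusted p = 4.59e-07). Among them were Tm2 (−1.34 ± 0.0947), the troponin T gene up (−1.32 ± 0.0985) and the myosin light chain gene Mlc2 (−0.91 ± 0.128). The ecdysone response had 17 rises and 2 falls among 40 genes (19 and 3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 8.87e-05). It included the nuclear receptor gene Eip78C (1.88 ± 0.144) and the transporter gene E23 (1.63 ± 0.16). The eIF4a 3′ minus 5′ difference on this array, 3.47, was the lowest of the 6 group values.

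Cuticle genes fell in 17 and rose in 7 of 50 cases on the array labelled P/act-Gal4 female (18 and 7 adjusted over the list alone). Their median was −0.18 (camera adjusted p = 0.00648, and adjusted p = 0.0556 with an estimated correlation). DNA replication and the cell cycle had 7 falls and 1 rise among 53 genes (7 and 1 adjusted over the list alone), with PCNA at −0.70 ± 0.136. Here the median was −0.13 (camera adjusted p = 0.0374, and adjusted p = 0.372 with an estimated correlation). Ribosomal proteins had 6 rises and 1 fall among 40 (6 and 1 adjusted over the list alone), with RpL37A at 0.48. This list had a median of 0.11 (camera adjusted p = 0.0374, and adjusted p = 0.404 with an estimated correlation). With quantile normalization the ribosomal median was 0.0097 (adjusted p = 0.668). The last 2 calls ended without act-Gal4 control female replicate 1 (adjusted p = 0.06 and 0.0521), and that of ribosomal proteins without P control female replicate 2 (adjusted p = 0.0711).

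Chromosome 4 gave 13 rises and 3 falls of 65 genes on the array labelled P/act-Gal4 female (17 and 4 adjusted over the list alone), with Zip102B at 1.5 ± 0.17 and dati at 0.91 ± 0.137, a sign that its other probeset did not share. Its median of 0.10 did not pass (camera adjusted p = 0.0813), but the chromosome did against the act-Gal4 control alone (median 0.13, adjusted p = 0.021) and with pooled controls (adjusted p = 0.0357). The named chromosome 4 list gave 7 rises and 2 falls (8 and 3 adjusted over the list alone, camera adjusted p = 0.28). Of the histone genes, His2Av stood at −0.16 (adjusted p = 0.314), BigH1 at −0.10 (adjusted p = 0.761) and cid at −0.17 (adjusted p = 0.304). Heterochromatin proteins gave 3 rises and 3 falls of 34 (median 0.072, camera adjusted p = 0.833), with ADD1 at 0.73 ± 0.141. Dosage compensation gave 3 and 0 of 10 (adjusted p = 0.156), pericentric genes 3 and 1 of 18 (5 and 1 adjusted over the list alone, adjusted p = 0.335) and the RNA interference pathway 1 and 2 of 23 (adjusted p = 0.408).

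Other lists did not pass on the array labelled P/act-Gal4 female. Members that passed are counted as values, since genes outside the lists passed too, and the counts are not read as results about the lists. Immune genes gave 5 rises and 4 falls (camera adjusted p = 0.522), with Drs, the gene of drosomycin, at 1.52 ± 0.113. Testis genes gave 14 rises and 0 falls (adjusted p = 0.131, and 0.0161 with quantile normalization), with Mst87F at 1.54 ± 0.134 and Mst84Dc at 1.14 ± 0.148. The 10 named genes with the largest male excess in controls also all stood higher on this array, by 0.39 to 1.14. They were picked on the same female controls, at levels not told apart from background. A cause of their rise was not tested. Midgut digestion gave 12 rises and 13 falls (12 and 23 adjusted over the list alone), with LManV at −1.46 and the glucosidase gene tobi at 1.92. Its adjusted p was 0.0544, but 0.0416 without act-Gal4 control female replicate 2, 0.0193 with bright probesets alone and 0.0271 with quantile normalization. Fat body gave 11 and 7 (adjusted p = 0.28), with Amyrel at 1.55 ± 0.113. Glue gave 6 and 5 (adjusted p = 0.952), with Sgs5bis at 1.63 ± 0.0957. Hemocytes gave 4 and 4 (adjusted p = 0.827), with a median of 0.043 and a mean of −0.022. Heat shock gave 3 and 2 (adjusted p = 0.522), with Hsp26 at 0.81 and Hsp60A at −0.83. Xenobiotic metabolism gave 9 and 12 (median 0.020, mean −0.043, adjusted p = 0.522), with Cyp6a23 at −1.45. Ovary genes gave 6 and 1 (adjusted p = 0.408), with the yolk protein gene Yp3 at −1.07. Sex determination gave 1 and 1 (adjusted p = 0.522), the nervous system 5 and 3 (adjusted p = 0.833) and imaginal disc 3 and 0 (adjusted p = 0.284). DNA damage and apoptosis gave 4 and 0 (adjusted p = 0.28), with the caspase gene Dronc at 0.99 ± 0.0988.

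In all, 2982 probesets passed on the array labelled P/act-Gal4 female, 1726 higher and 1256 lower, of which 358 differed at least 2-fold. The array lay beyond all 4 control arrays for 51% of all probesets. Chance would give 40% if all female arrays were exchangeable, which replicates of a cross are not, so no excess over chance is read. Among the 2982 called, the number was 2829 (94.9%), a share that the test itself raises. The count was 445 with both controls pooled, 1517 with the female arrays alone in the fit and 1434 against each control separately. Examples from the lists that did not pass with pooled controls were tobi (adjusted p = 0.0573), Mst84Dc, E23, Cyp6a23, RpL37A, PCNA, ADD1, Eip78C, Yp3, Drs, Hsp26, Amyrel and Zip102B (0.358). Means of 1 or both controls were at most 4.16 for ADD1, Mst84Dc, Eip78C, tobi and Zip102B, so that their rises are lower bounds. The lone array was assumed to vary like the other groups. Against the P control alone the calls of cuticle (adjusted p = 0.246), DNA replication (0.25) and ribosomal proteins (0.182) ended, as did that of cuticle with pooled controls (0.109) and that of ribosomal proteins with bright probesets alone (0.0749). Against the act-Gal4 control alone, dosage compensation (0.0422), midgut digestion (0.00511), hemocytes (median −0.026, 0.0440) and xenobiotic metabolism (median −0.046, 0.0422) passed, the last 2 with medians that had turned. Over camera's alternatives adjusted p ran from 8.7e-04 to 0.246 for cuticle, from 0.00511 to 0.372 for DNA replication and from 0.0108 to 0.668 for ribosomal proteins.

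The changes in the 2 sexes were then compared. Across probesets, which are not independent replicates, the log2 changes in males and on the array labelled P/act-Gal4 female had a Pearson correlation of 0.439 and a Spearman correlation of 0.36. The differences between controls in the 2 sexes had 0.511 and 0.342. Of the 5482 probesets called in males, 3922 (71.5%) had the same sign on that array, against 63.8% of all probesets. Both calls were made for 1832 probesets, with 1014 higher in both, 535 lower in both and 283 in opposite directions. Independent calls would give 281.9 higher and 161.7 lower in both. The calls are not independent, since both tests use the same spread per probeset, so the excess over these numbers is overstated. Jig, CtsL3, Eig71Ed, e and 18SrRNA-Psi:CR41602 were among the 10 largest rises of named genes in both sexes.

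**Figure D3:**
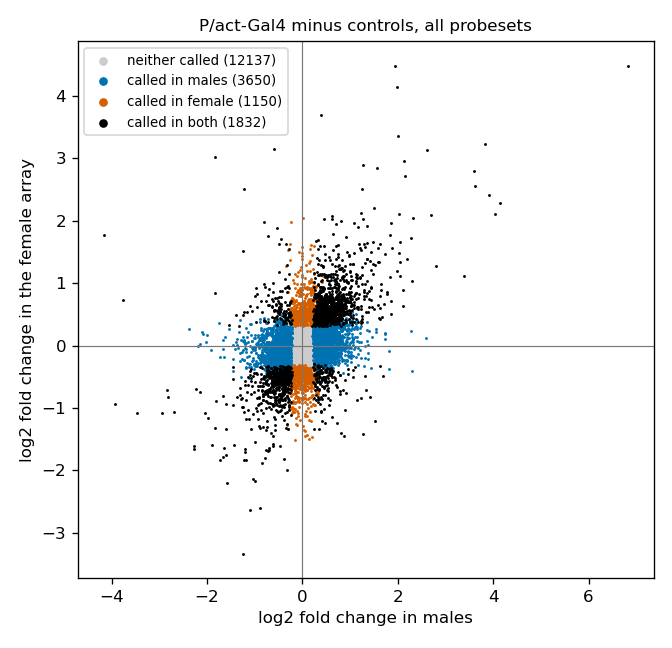
Log2 change of each probeset in males (horizontal) and on the array labelled P/act-Gal4 female (vertical), each against the mean of both controls of the sex, coloured by where it passed the test. Of the 1832 probesets called in both, 1014 lie in the upper right and 535 in the lower left.

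Whether the change in males differed from that on the array labelled P/act-Gal4 female was tested directly, as the male change minus the female change, which is the question the series title raises. Among named genes the largest difference was that of ImpE2, at −4.50 ± 0.129 (adjusted p = 6.8e-09), with −3.76 in males and 0.73 in the female array. Drsl5 (−3.73 ± 0.186) and Drs (−2.76 ± 0.143), 2 genes of the drosomycin family, fell in males and rose in the female array. Drsl2 of that family, named after its values were seen, rose in both, by 0.75 (adjusted p = 0.000554) and by 0.98 (adjusted p = 0.00109), but stood at −0.13 in males against the P control alone (adjusted p = 0.546). The antimicrobial gene Def rose in males, with a difference of 2.47 ± 0.141. Further negative differences were those of nol (−3.0), the nuclear receptor gene Eip78C (−2.42), Lcp9 (−2.38), Hsp68 (−2.31), Alp7 (−2.26), e (−2.16) and the glue gene Sgs5bis (−2.13). Positive differences were those of the neuropeptide-like gene Nplp2 (2.32), LManIII (2.20), the serine protease gene Phae2 (2.19), Apoltp (2.01) and 18SrRNA-Psi:CR41602 (1.93). So were those of the trypsin gene lambdaTry (1.65), Cyp6w1 (1.64), the insulin-like peptide gene Ilp8 (1.58) and the ornithine decarboxylase gene Odc2 (1.57). The lower male means of ImpE2, nol, Alp7, Def and 18SrRNA-Psi:CR41602, at 3.24 to 3.84, were not told apart from background, nor were those of lambdaTry on the female array and of Eip78C and e in P control females, so that these differences are lower bounds in size, and Ilp8 was dim in every group, at 4.34 or below. The value of e turned to 0.30 against the act-Gal4 control alone (adjusted p = 0.273). With both controls pooled the differences of Cyp6w1 (adjusted p = 0.107), Drs, Eip78C, lambdaTry, Odc2, Lcp9, Drsl5, Hsp68, LManIII, Alp7 (0.652) and e did not pass.

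Among lists, heterochromatin proteins were lower in males relative to the array labelled P/act-Gal4 female, with 5 of 34 genes lower and 0 higher (10 and 1 adjusted over the list alone). Their median was −0.24 (camera adjusted p = 0.00796, and adjusted p = 0.144 with an estimated correlation), with HP4 at −0.96 ± 0.174 and borr at −0.76 ± 0.138. Testis genes gave 11 lower and 1 higher of 54 (15 and 3 adjusted over the list alone), with vis at −1.45 ± 0.232, dim in all females, and Mst98Ca at −1.01 ± 0.196, dim in female controls. Their median was −0.30 (camera adjusted p = 0.00337, and adjusted p = 0.119 with an estimated correlation, as also for imaginal disc, heat shock and glue). Imaginal disc genes gave 7 lower and 0 higher of 29 (9 and 0 adjusted over the list alone, median −0.23, camera adjusted p = 0.00796), with dac at −1.41 ± 0.201 and en at −1.31 ± 0.128. Heat shock gave 6 lower and 1 higher of 13 (6 and 1 adjusted over the list alone, median −0.24, camera adjusted p = 0.00743), with Hsp26 at −1.52 ± 0.137 and Hsp27 at −1.26 ± 0.126. Glue gave 7 lower and 3 higher of 16 (8 and 3 adjusted over the list alone, median −0.42, camera adjusted p = 0.0186), with Sgs1 at −1.41. DNA replication gave 5 lower and 0 higher of 53 (5 and 0 adjusted over the list alone), with CycB3 at −0.96. Its median was −0.16 (camera adjusted p = 0.0205, and adjusted p = 0.187 with an estimated correlation), a call that ended without P/act-Gal4 male replicate 1 (adjusted p = 0.057).

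Other lists were higher in males relative to that array. Muscle gave 8 higher and 0 lower of 24 (11 and 0 adjusted over the list alone), with Mlc2 at 1.23 ± 0.162 and Msp300 at 0.98 ± 0.131. Its median was 0.22 (camera adjusted p = 0.00337, and adjusted p = 0.119 with an estimated correlation, as also for glycolysis and hemocytes). Glycolysis gave 5 and 0 of 17 (7 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.00796), with Hex-A at 1.18 ± 0.129. Hemocytes gave 7 higher and 1 lower of 23 (9 and 1 adjusted over the list alone, median 0.059, camera adjusted p = 0.0186), with NimC1 at 1.28 ± 0.154 and PPO2 at 1.08 ± 0.118. Mitochondrial respiration gave 8 higher and 0 lower of 75 (8 and 0 adjusted over the list alone), with Cyt-c1 at 0.75. Its median was 0.14 (camera adjusted p = 0.00796, and adjusted p = 0.307 with an estimated correlation). Xenobiotic metabolism gave 14 and 2 of 75 (20 and 7 adjusted over the list alone), with Cyp6a17 at 1.02 ± 0.129. The median was 0.071 (camera adjusted p = 0.0341, and adjusted p = 0.138 with an estimated correlation), and the call ended without P control female replicate 2 (adjusted p = 0.067). The ecdysone response, with 3 higher and 10 lower of 40 (3 and 11 adjusted over the list alone), did not pass (camera adjusted p = 0.0535), but did without P control male replicate 1 (0.05, just under the threshold before rounding) or P/act-Gal4 male replicate 2 (0.0457), and with quantile normalization (0.0471). Chromosome 4, with 5 and 0 of 65 (median 0.090, adjusted p = 0.325), did not pass either, and dosage compensation had no gene that passed (adjusted p = 0.839).

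**Figure D4:**
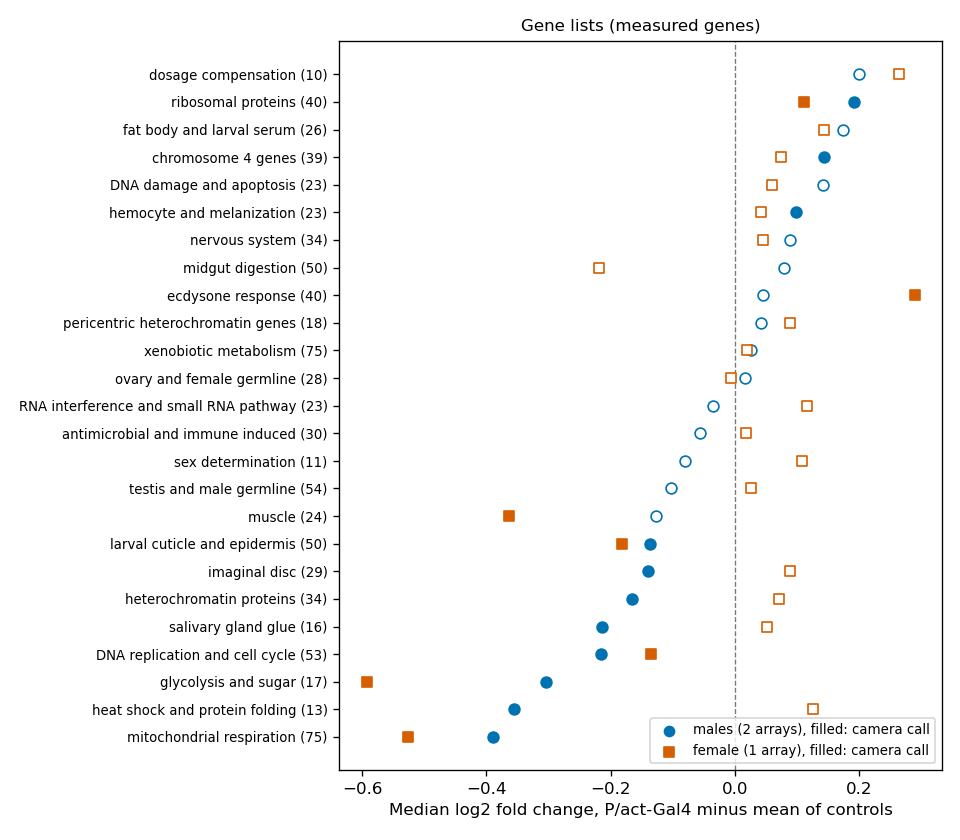
Median log2 change of the 25 tested gene lists in males (circles) and on the array labelled P/act-Gal4 female (squares), each against the mean of both controls of the sex; filled symbols passed camera with the preset correlation. Mitochondrial respiration is low in both, at −0.39 and −0.53.

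In all, 2232 probesets passed the test of the difference, 1119 higher and 1113 lower in males, and 440 of them by at least 2-fold. The count was 207 with both controls pooled and 1386 without P/act-Gal4 male replicate 1. Examples from the lists that did not pass with pooled controls were borr (adjusted p = 0.0685), Hsp27, Cyp6a17, Mst98Ca, Hsp26, Msp300, HP4, Hex-A, Cyt-c1, NimC1 and PPO2 (0.861). Differences of Mst98Ca, dac and NimC1 rest on means of at most 4.16 and are lower bounds in size. Against the act-Gal4 control alone the medians of muscle (−0.060, adjusted p = 0.328) and mitochondrial respiration (−0.076, adjusted p = 0.410) turned. Calls of glycolysis (adjusted p = 0.453), testis (0.103), heat shock (0.103) and xenobiotic metabolism (0.345) ended there, as did those of glue (0.214), hemocytes (0.069) and DNA replication (0.0944) against the P control alone. With pooled controls the calls of heat shock (0.0697), hemocytes, xenobiotic metabolism, mitochondrial respiration and glycolysis (each 0.0559) ended. Against the P control alone, immune genes (0.027), the ecdysone response (0.0148) and midgut digestion (0.0129) passed, and with bright probesets alone the ecdysone response (0.0178) and midgut digestion (0.0283). Over camera's alternatives for the 9 lists named with 1 control, adjusted p reached down to 0.0128 for DNA replication and lower for the others, and up to 0.119 for testis, heat shock and hemocytes and higher for the others.

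Control larvae gave the baseline difference between males (n = 4) and females (n = 4). Genes of the male germline were far higher in males. The sperm aminopeptidase genes S-Lap7, S-Lap8 and S-Lap2 were higher by 7.24 ± 0.0801 on the log2 scale (151-fold, adjusted p = 2.36e-14), by 104-fold and by 80.6-fold. The Mst genes Mst84Da, Mst98Ca and Mst84Dc were higher by 87.2-fold, 84.2-fold and 73.0-fold. Other such genes were salto (114-fold), exu (86.6-fold), tHMG1 (82.7-fold) and ocn (77.6-fold). Female means of these 10 genes, at 2.75 to 4.16, were not told apart from background, so that the folds are lower bounds. Lower in males were the yolk protein gene Yp3 (−2.51 ± 0.0769, at least 5.70-fold, as the male mean was 3.46) and the cuticle genes Cpr47Eg (at least 5.06-fold), Cpr47Ec (3.25-fold) and Cpr11B (at least 2.59-fold), with 1 male control group at 3.99 for Cpr47Eg and at 4.16 for Cpr11B. So were the maltase gene Mal-A3 (3.47-fold), sphe (3.17-fold), the glue gene ng1 (3.08-fold), Nplp2 (3.03-fold), the protease gene Ser6 (2.79-fold) and Odc2 (2.71-fold). Of 54 testis genes, 39 were higher and 1 lower in males (40 and 1 adjusted over the list alone). Their median difference was 1.87 (camera adjusted p = 6.12e-19, and adjusted p = 0.0152 with an estimated correlation). The median level of these genes lay between 4.97 and 5.57 on the male arrays and between 3.03 and 3.18 on the female arrays, as titles and gender labels give the sexes. The description label reads male for all.

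Some genes within lists of general function were far higher in males, with female means of 2.82 to 3.71 that make the folds lower bounds. In mitochondrial respiration, ATPsynCF6L, COX5BL and COX4L were 23.2-fold, 22.6-fold and 13.8-fold higher in males, though 46 of 75 genes were lower and 20 higher (48 and 20 adjusted over the list alone). The median of this list was −0.22, the mean 0.37 and camera gave no call (adjusted p = 0.802), whereas with act-Gal4 controls alone the list passed with its median turned (0.080, adjusted p = 0.00298). In ribosomal proteins, RpL10Aa and RpS19b were 8.54-fold and 7.43-fold higher. There the median was −0.020 and the mean 0.34 (camera adjusted p = 0.129), and the median turned to 0.0096 with quantile normalization. Among heat shock genes 8 of 13 were higher (8 adjusted over the list alone), with Hsc70-2 at 10.7-fold. Their median was 0.20 (camera adjusted p = 0.00308, and adjusted p = 0.0967 with an estimated correlation). Among heterochromatin proteins HP6 was 4.57-fold higher (median 0.11, camera adjusted p = 0.119, turning to −0.051 with arrays shifted to a common median).

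Lists of metabolism and barrier tissues were lower in control males than in control females. Of all 11982 genes, 4903 were lower and 2688 higher in control males, against which the counts of members are to be read. Xenobiotic metabolism had 54 lower and 4 higher of 75 (56 and 4 adjusted over the list alone), with Cyp6w1 at −1.15. Its median was −0.43 (camera adjusted p = 1.73e-05, and adjusted p = 0.0485 with an estimated correlation). Midgut digestion had 33 lower and 2 higher of 50 (34 and 2 adjusted over the list alone), with LManIII at −1.91. Here the median was −0.37 (camera adjusted p = 1.73e-05, and adjusted p = 0.147 with an estimated correlation). Cuticle gave 34 lower and 5 higher of 50 (35 and 5 adjusted over the list alone, median −0.32, camera adjusted p = 0.00308, and adjusted p = 0.07 with an estimated correlation). Hemocytes gave 15 and 0 of 23 (median −0.40, camera adjusted p = 0.00308, and adjusted p = 0.0849 with an estimated correlation), with PPO1 at −1.03 (a lower bound in size, as the P control male mean was 3.69), which did not pass with pooled controls (adjusted p = 0.346). Glycolysis gave 13 and 0 of 17 (median −0.26, camera adjusted p = 0.0184, and adjusted p = 0.155 with an estimated correlation). Genes of the X had a median of −0.22, with 305 higher and 989 lower of 1869 (adjusted p = 0.057), and passed with bright probesets alone (median −0.25, adjusted p = 0.00145).

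In all, 11398 probesets passed between male and female controls, 3058 higher and 8340 lower in males. The median over all probesets was −0.17, and shifting the arrays to a common median moved it to −0.33 and the counts to 2455 and 13539, so that changes of that size are read relative to this shift. With act-Gal4 controls alone the calls of heat shock (adjusted p = 0.370) and glycolysis (adjusted p = 0.451) ended, and that of glycolysis also with quantile normalization (0.0883) and pooled controls (0.126). Immune (0.00356) and nervous system genes (0.0193) passed there, and muscle did with P controls alone (0.00575).

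The 2 controls, which carry 1 transgene each, were compared as the background of the other comparisons. In males, act-Gal4 controls exceeded P controls in the prophenoloxidase genes PPO1 (3.03 ± 0.111, at least 8.18-fold) and PPO2 (5.69-fold) and in Cyp4e3 (3.29 ± 0.106, at least 9.75-fold). They were also higher in Cpr47Eg (at least 5.82-fold) and LManIII (5.51-fold), and lower in Hsp68 (−2.40 ± 0.0873, 5.28-fold). In females they exceeded P controls in e (by at least 4.80), Drsl5 (3.83 ± 0.131, 14.2-fold), PPO1 (6.78-fold) and Cyp4e3 (6.62-fold), and were lower in ng2 (−2.04 ± 0.113, 4.12-fold). Values given as at least rest on P control means not told apart from background. Mitochondrial respiration was higher in act-Gal4 than in P control males, 32 and 4 of 75 (35 and 6 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.00023, and adjusted p = 0.188 with an estimated correlation). In females the list was lower, 0 higher and 21 lower (1 and 28 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 9.26e-07, and adjusted p = 0.199 with an estimated correlation). Chromosome 4 had medians of −0.012 in males, turning to 0.0039 with quantile normalization, and 0.0090 in females, turning to −0.0080 (adjusted p = 0.919 and 0.934). The eIF4a 3′ minus 5′ difference was lower by 0.65 in act-Gal4 than in P control males. The 1 measured transgene marker, the yellow gene (y), was dim on all arrays, at 2.43 to 2.91.

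The comparison of controls gave 3455 probesets in males (1885 higher, 1570 lower) and 3110 in females (1467 and 1643). The male count was 1901 without act-Gal4 control male replicate 1, 1946 without act-Gal4 control male replicate 2 and 2036 without P control male replicate 2. The female count was 1612 with the female arrays alone in the fit.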

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

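Of the tests of explanations in this part, those of RNA integrity, of the lower HP1 transcript, of a mislabelled or lone female array, of differences between crosses and of the control probeset were chosen after the results were seen; the tests of the comparisons and lists, the splits and the match on length and level were chosen before.

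Chromosome 4 genes were higher in P/act-Gal4 males, with a median log2 change of 0.23 (adjusted p = 9.51e-05, and adjusted p = 0.507 with an estimated correlation) and 51 of 65 genes above 0. Their median deviation was 0.10 and 0.18 on the 2 P/act-Gal4 male arrays, 0.12 on the array labelled P/act-Gal4 female and −0.079 to −0.012 on the 8 control arrays. The tables argue against gene length and expression level. Of 10000 random lists matched on both, which take genes as uncorrelated, 0 reached a median of 0.23 (highest 0.21). They also argue against RNA integrity, if its effect is proportional to the eIF4a 3′ minus 5′ difference, which was not tested. The male controls differed in this measure by −0.65, where 0.16 would be in proportion, yet their chromosome 4 median was −0.012. Its 95% interval, −0.059 to 0.071, takes genes as independent and holds no spread between arrays. In act-Gal4 control, P control and P/act-Gal4 males the same measure was 3.32, 4.59 and 3.31 for GAPDH and 3.34, 3.75 and 2.95 for Act5C. The lower HP1 transcript could be the cause and stays open: the difference of the shift from that of the array with an undiminished HP1 transcript did not pass (adjusted p = 0.325), which excludes neither view. A difference between crosses other than HP1 also stays open: 11 of the 34 chromosome 4 genes called (32.4%) differed between the male controls too, a share no higher than the 35.4% among all probesets called.

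The HP1 transcript was not lower on the array labelled P/act-Gal4 female, and the difference from males, −0.53, passed the test with adjusted p = 0.0467, though not against the P control alone (adjusted p = 0.189), with controls pooled (0.327), with quantile normalization (0.0582) or without any 1 of 8 arrays (0.0592 to 0.162). The tables argue against a mislabelled act-Gal4 control female, since at least 257 probesets lay over 1 (log2) from either such array, against at most 4 between replicates, and against a mislabelled P control female, since AFFX-Dm-K01486-1_at read 9.42 on this array and at most 3.53 on the P controls. Too few arrays to see a fall stays open: the lower 95% bound of the female change was −0.27, or −0.37 with both controls pooled, and the male interval reached up to −0.32. An effect of sex may be present, but with 1 array it stays open together with a weaker action in this one sample. The signal of AFFX-Dm-K01486-1_at, which followed act-Gal4, was 9.42 on this array and 10 and 10.1 on the P/act-Gal4 male arrays. On the act-Gal4 control arrays of both sexes it was 8.79 to 8.95. Whether this signal bears on the HP1 transcript was not tested. Whether the probeset also reads RNA made by the HP1-21 construct was not tested.

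Many probesets were called in P/act-Gal4 males, 5482, and 35.4% of them also differed between the male controls, against 11.4% of the others (ratio 3.11). Both tests use the same spread, and others of like residual spread and mean level gave 24.7% to 25.3% (ratio 1.40 to 1.43, under the 1.5 set for the test). A candidate explanation for a part of the calls, a difference between crosses apart from HP1, therefore stays open. All 2447 probesets that passed with both controls pooled were among the 5482. Leftover differences between crosses that both controls share cannot be measured in this design, so an action of lower HP1 on the rest stays open and untested.

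Between male and female controls, 7070 probesets passed in a fit of the 8 control arrays in 2 groups, and 1 of the 35 splits into 4 and 4 arrays gave as many, the real one. The highest other split, by control genotype, gave 395. Every split but the real one mixes the sexes within its groups, so the sex difference enters its error and lowers its count. The lowest share that the 35 splits allow is 1 of 35. The splits therefore cannot exclude chance for this count. The median level of the 54 testis genes, a list fixed before the data were examined, was 5.18 to 5.57 on the male control arrays. On the female control arrays it was 3.03 to 3.14, which argues against chance for the sex difference of these genes.

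A difference between males and the array labelled P/act-Gal4 female in the change against controls was the reason to list the following values, each past the test of the difference. The count of such probesets was 2232. Male minus female log2 changes were 2.47 for Def, 2.32 for Nplp2, 2.20 for LManIII, 2.19 for Phae2, 2.01 for Apoltp, 1.93 for 18SrRNA-Psi:CR41602, 1.65 for lambdaTry, 1.64 for Cyp6w1, 1.58 for Ilp8 and 1.57 for Odc2. They were −4.50 for ImpE2, −3.73 for Drsl5, −3.0 for nol, −2.76 for Drs, −2.42 for Eip78C, −2.38 for Lcp9, −2.31 for Hsp68, −2.26 for Alp7, −2.16 for e, −2.13 for Sgs5bis and −0.53 for the HP1 gene. With controls pooled, 11 of the first 20 and the HP1 gene did not pass: LManIII, lambdaTry, Cyp6w1 (adjusted p = 0.107), Odc2, Drsl5, Drs, Eip78C, Lcp9, Hsp68, Alp7 (0.652) and e, which also turned to 0.30 against the act-Gal4 control alone (adjusted p = 0.273). The differences of ImpE2, nol, Alp7, Def, Eip78C, e, 18SrRNA-Psi:CR41602 and lambdaTry rest on means not told apart from background and are lower bounds in size, and Ilp8 was dim in every group. Medians of the lists were −0.24 for heterochromatin proteins, −0.16 for DNA replication and cell cycle, −0.24 for heat shock and protein folding, −0.30 for testis and male germline, −0.42 for salivary gland glue and −0.23 for imaginal disc. They were 0.22 for muscle, 0.059 for hemocyte and melanization, 0.071 for xenobiotic metabolism, 0.14 for mitochondrial respiration and 0.20 for glycolysis and sugar. With an estimated correlation none of the 11 lists passed (adjusted p = 0.119 to 0.307), and against the act-Gal4 control alone the medians of muscle (−0.060) and mitochondrial respiration (−0.076) turned.

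A signal in an Affymetrix control probeset, which the comparisons do not use, was listed because it was absent from some control arrays: AFFX-Dm-K01486-1_at read 8.79 to 10.1 (log2) on the 7 arrays with act-Gal4 and 2.91 to 3.53 on the 4 P control arrays, at least 38.4-fold apart. Among arrays with act-Gal4 it read 8.79 to 8.95 in controls, 10 and 10.1 in P/act-Gal4 males and 9.42 on the array labelled P/act-Gal4 female.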

How the results depend on the processing

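The counts against each control separately, those with P/act-Gal4 arrays beyond all 4 control arrays, and the list results with pooled controls were chosen after seeing the data; all other alternatives were chosen before. No paired analysis was possible because the labels give no replicate or population numbers that join arrays. A cause was not tested for any value below, except where fewer probesets, fewer arrays or a stricter threshold make a smaller count.

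Counts of called probesets moved with a change of at least 1 on the log2 scale, to 397 in males, 358 on the array labelled P/act-Gal4 female, 440 for their difference, 1573 for sex in controls, and 304 and 379 for the controls in males and females. With both controls pooled, which puts their differences into the error, they were 2447, 445 and 207; against each control separately 2871 and 1434; with female arrays alone 1517 and, for the controls, 1612; and with bright probesets alone 6574 for sex in controls. Leaving out 1 array at a time gave 3392 to 5905 in males (lowest without P/act-Gal4 male replicate 2), 2613 to 3503 in females, 1386 to 2594 for their difference (lowest without P/act-Gal4 male replicate 1), 9607 to 11400 for sex in controls, 1901 to 3842 for the controls in males (lowest without act-Gal4 control male replicate 1, then 1946 without act-Gal4 control male replicate 2 and 2036 without P control male replicate 2) and 2180 to 3110 in females. The highest of these counts for sex in controls is a rounded figure. The correlation between the sexes was 0.399 with 1 probeset per gene, 0.485 against the act-Gal4 control alone and 0.404 to 0.456 with 1 array left out.

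The fall of the HP1 transcript in males kept its call under all alternatives tried, at −0.69 to −0.37 with 1 array left out, and the female value, at −0.027 to 0.024, never passed. The difference between the sexes lost its call with quantile normalization (−0.53, adjusted p = 0.0582), against the P control alone (−0.38, adjusted p = 0.189), with controls pooled (−0.53, adjusted p = 0.327) and with each of 8 arrays left out, all but P control female replicate 2 and P/act-Gal4 male replicate 1 (−0.69 to −0.37 over all arrays left out, adjusted p = 0.0592 to 0.162 for these 8). Results that turned were the sex difference of e against the act-Gal4 control alone (0.30, adjusted p = 0.273), Drsl2 in males against the P control alone (−0.13, adjusted p = 0.546), the sex difference of the effect in mitochondrial respiration against the act-Gal4 control alone (−0.076, adjusted p = 0.41), the median of muscle in the same comparison and setting (−0.060, adjusted p = 0.328, camera's direction kept), and mitochondrial respiration between control sexes with fry (median −0.22, fry direction up, adjusted p = 7.3e-05) and against the act-Gal4 control alone (0.080, adjusted p = 0.00298). In females, medians of hemocytes (−0.026, adjusted p = 0.0440) and xenobiotic metabolism (−0.046, adjusted p = 0.0422) turned and passed against the act-Gal4 control alone.

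Over all alternatives, 4370 values of named genes stayed on their side of the threshold without a called value turning, 85 lost a call, 15 gained one and 2 turned. Of the 85, 68 were lost with both controls pooled, where the other 119 stayed. For lists, by the direction of the test, the numbers were 1249, 89, 59 and 3, with 30 of the 89 lost under camera with an estimated correlation and 16 without single arrays. List medians changed sign 48 times, 43 of them where neither value was called. For chromosomes 284 were kept, 1 was lost and 3 were gained. Dim probesets were not told apart from background, which limits changes at low level.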

Other observations

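The tests of the control probeset were chosen after its values were seen, and those of unnamed probesets and of mitochondrial genes before theirs.

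Fat body and hemocyte genes differed between the 2 controls in both sexes. Fat body and larval serum genes were higher in act-Gal4 than in P controls, 12 and 2 of 26 in males (13 and 2 adjusted over the list alone; median 0.28, camera adjusted p = 5.56e-05; adjusted p = 0.0441 with an estimated correlation) and 12 and 3 in females (median 0.21, camera adjusted p = 0.000457; adjusted p = 0.082 with an estimated correlation). The starch enzyme gene Amyrel stood at 1.40 ± 0.101 and 1.46 ± 0.101, the fatty acid synthase gene FASN1 at 1.17 ± 0.0908 in males and the odorant binding protein gene Obp99b at 1.46 ± 0.0829 in females. Hemocyte and melanization genes were higher too, 8 and 0 of 23 in males (9 and 0 adjusted over the list alone; median 0.17, camera adjusted p = 0.000632; adjusted p = 0.0441 with an estimated correlation) and 10 and 1 in females (11 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 5.2e-05; adjusted p = 0.082 with an estimated correlation), with the clotting gene fon at 1.43 ± 0.0841 and 1.82 ± 0.0841. The neuropeptide gene Dh44 was lower in act-Gal4 controls of both sexes, at −1.61 ± 0.142 and −1.22 ± 0.142 (the latter a lower bound in size, as the mean of 3.87 was not told apart from background), and the glutathione transferase gene GstE7 higher, at 1.78 ± 0.123 and 1.75 ± 0.123.

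In males, act-Gal4 controls were also higher in glycolysis (11 and 2 of 17, median 0.42, camera adjusted p = 0.00023; adjusted p = 0.0441 with an estimated correlation), muscle (10 and 0 of 24, 12 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.00159; adjusted p = 0.0441 with an estimated correlation) and xenobiotic metabolism (27 and 4 of 75, 28 and 6 adjusted over the list alone, median 0.18, camera adjusted p = 0.00023; adjusted p = 0.0441 with an estimated correlation). Heat shock genes were lower, 0 and 6 of 13 (0 and 9 adjusted over the list alone; median −0.30, camera adjusted p = 2.45e-05; adjusted p = 0.0441 with an estimated correlation), with the chaperone genes stv at −1.55 ± 0.0925 and DnaJ-1 at −1.12 ± 0.0919. Probesets with no gene name were among the largest changes in P/act-Gal4 males. The 2 with the largest rises rose by 6.82 ± 0.157 and by 3.90 ± 0.114, with 4.48 and 2.41 on the array labelled P/act-Gal4 female. The 2 with the largest falls stood at −2.95 ± 0.0751 and −2.82 ± 0.0952. The first of these also stood at −2.22 in act-Gal4 against P control males. These 4 were chosen after their values were seen.

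A hypothesis was that AFFX-Dm-K01486-1_at may read the transcript of the driver transgene. It needs every array with act-Gal4 to lie above every array without, and the lowest of the 7 lay 38.4-fold above the highest of the other 4, so the hypothesis stays open.

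A hypothesis was that probesets with no gene name are in excess among the rises of at least 2-fold in P/act-Gal4 males. They were fewer, 47 of 241 (19.5%) against 25.2% of the other probesets (Fisher's exact test, two-sided p = 0.0435), and fewer still among the falls, 14 of 156 (8.97%, two-sided p = 3.8e-07 by the same exact test), so the values speak against it.

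A hypothesis was that the lower median of mitochondrial respiration in both sexes may be a general fall of bright transcripts. Of 10000 random lists matched on level, which take genes as uncorrelated, 0 had a median as low as −0.39 in males (lowest −0.15). The median over these lists was 0.046, so genes of like level did not fall in general, which argues against the hypothesis in males. How far the fall of the list itself exceeds chance is not settled by such lists (camera adjusted p = 0.105 with an estimated correlation).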
